A study of Mus musculus with 12 samples.

How the data were processed

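Total RNA from mouse striatum (labelled striatal cells, background C57/BL6) was measured in 12 libraries, 3 for each of the genotypes WT, Q175HD, SUMO-KO and Q175HD_SUMO-KO. Per the labels, RNA was isolated with the miRNeasy Mini Kit and libraries were made with the NEBNext Ultra II directional kit after depletion of ribosomal RNA. The submitters' processing notes name cutadapt 2.10, STAR 2.5.2a, Bowtie 1.1.2 and DESeq2 (version not given), with the builds mm10 and GRCm38. Their roles and parameters, the gene counting tool and the strand counted are not given in the sources used here.

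The deposited count table holds whole-number read counts per Ensembl gene and library, without normalization, for 53465 genes, and it held 0 columns of other series. The log2 fold changes of the authors' deposited tables are DESeq2 results per gene, per the file headers. The p-values and adjusted p-values in the same deposited tables are also DESeq2 output per the file headers. The authors' values were used only for comparison, and the deposited normalized and TPM tables were not used here. Genes were placed on GRCm38 with GENCODE M21, in which 53360 of the identifiers and 17772 of the genes tested were found. There were 112 duplicated symbols, so genes were handled by identifier.

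The raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17796, and libraries were scaled by TMM. A model with 4 group means was fitted to all 12 libraries with the quasi-likelihood method and robust dispersion (common BCV 0.171). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold, in each of 7 comparisons: the 6 pairs of genotypes and the interaction of knock-in and SUMO-1 loss. The effect of the knock-in averaged over SUMO-1 status and that of SUMO-1 loss averaged over Htt status came from the same fit. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM used a prior count of 2. A fold against a group with 0 reads was bounded with a floor of 3 counts over the group, the limit at a confidence level of 0.95. Intervals and floors cover counting error only.

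There were 29 gene lists, written from textbook knowledge. They were SUMO conjugation and deconjugation; striatal projection neuron; direct pathway and indirect pathway neuron; immediate early; homeobox and other developmental transcription factor; beta protocadherin; microglia; cytokine and innate inflammation; interferon response; autophagy; lysosome; heat shock and chaperone; cholesterol biosynthesis; nuclear-encoded oxidative phosphorylation; mitochondrially encoded; cytosolic ribosomal protein; and glutamate and GABA receptor genes. Marker lists covered the astrocyte, myelinating oligodendrocyte, oligodendrocyte precursor, endothelial cell and pericyte, choroid plexus, ependymal, cortical excitatory neuron, thalamic, septal and pallidal neuron, striatal interneuron, meningeal fibroblast and blood cell. The projection neuron list shares 6 genes with each pathway list, the indirect pathway and receptor lists share 1, the developmental and thalamic lists share 2, and the oxidative phosphorylation and interneuron lists share 1. Lists with at least 5 tested genes were tested with limma 3.58.1 by camera (preset correlation 0.01), adjusted over the 29 lists of a comparison, and again with an estimated correlation and by fry. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. The mean of a list per library is the mean log2 CPM of its tested genes around the WT mean of each gene, compared by a two-sided exact permutation test whose smallest p is 0.1.

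Agreement between comparisons that share no library was measured by Pearson and Spearman correlations across genes and by shared calls beside the number that chance gives. The size of the knock-in effect with and without SUMO-1 was compared over genes called for the averaged knock-in effect, by the median interaction signed by the averaged effect and by fry. Calls within 10 Mb of Htt were counted with a two-sided Fisher's exact test, leaving out Htt, with windows of 5 and 20 Mb as alternatives.

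Genes were named by a rule. Genes fixed in advance, among them Htt and Rasd2, were always named. The 12 largest rises and 12 largest falls were named among calls with a mean count of at least 50 and no overlap between the groups, leaving out predicted genes (Gm numbers, Rik names, bare identifiers), pseudogenes, Xist, Tsix and Y-linked genes. Called members of each list were named, up to 4 per direction, and where fewer than 2 passed, up to 3 members by mean expression were eligible as values. Genes outside the rule are said to be chosen after their values were seen.

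The lists, tests, naming rule and the following other settings were fixed before the data were examined: median-ratio size factors, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0, limma voom with sample quality weights, only the 6 libraries compared, the replicate number as a block, a minimum absolute log2 fold change of 0.5, each library left out in turn, genes for the size comparison chosen at an adjusted p under 0.001, and a prior count of 0.5. Settings added after seeing the data were the sex of the library or the cortical list mean as a covariate, removal of the GC and length trend, male libraries only, and fits without WT 1 and 2 or without SUMO-KO 1 and 2. A count was taken as moved when it changed by more than 1.5 times. Other splits of the 6 libraries of a comparison were counted in full, and 100 splits were drawn with a fixed seed for the interaction. The cortical list was also tested for varying together, by the mean correlation of its members' deviations from the group means in the 9 libraries other than WT, against 10000 random lists matched on mean log2 CPM in 20 bins. A crowding test used the 50 genes with the smallest p, a distance of 2 Mb, 10000 random draws and 1 chromosomal region left out. Some genes that the rule names, and tests of calls near 1 of them, are not reported here, while counts of calls and list tests include them. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

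The tests were also run on simulated data, in which genes varied independently of each other. The spread of each simulated gene was set by the trend over mean expression, not by the gene's own spread. Changed genes were drawn from those with a mean count of at least 50. Of 100 genes changed 2-fold, 81 were recovered for Q175HD against WT, 86 for SUMO-KO against WT and 59 for the interaction, and of 100 changed 1.5-fold, 30, 40 and 12 were. Unchanged genes were called 8, 9 and 2 times among 17533, 17549 and 17568 genes run. Lists of random genes had a camera p of 0.612, 0.827 and 0.701. These runs hold no correlation between genes and no structure of the samples apart from genotype. They therefore do not show how calls or list tests behave where those exist.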

Results

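Total RNA from the mouse striatum was sequenced after depletion of ribosomal RNA, in 4 genotypes with 3 libraries each. WT animals carried neither change, Q175HD animals carried an expanded CAG repeat knocked into the huntingtin gene Htt, SUMO-KO animals were labelled as lacking SUMO-1, a small ubiquitin-like protein modifier, and Q175HD_SUMO-KO animals carried both changes. Reads assigned to genes summed to 12213078, 11994900 and 13926488 in WT libraries 1, 2 and 3, and to 14050353, 12976828 and 14846019 in Q175HD. They summed to 9379594, 10120161 and 14714746 in SUMO-KO, and to 12195985, 11237097 and 17226419 in Q175HD_SUMO-KO. Of 53465 genes, 17796 had enough reads to be tested. No pair of replicates was a repeat of the same library, since the chi-square per degree of freedom between replicates of a group ranged from 9.28 to 30.57. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples. A two-sided exact permutation test of 3 libraries against 3 cannot give a p below 0.1.

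Xist, the transcript that silences an X chromosome in females, was abundant in WT 2, SUMO-KO 2 and Q175HD_SUMO-KO 2, with 18092, 19854 and 18386 reads, and these libraries had at most 2 reads of the Y-linked gene Ddx3y. The other 9 libraries had at most 51 Xist reads and at least 754 Ddx3y reads, and all 3 Q175HD libraries were among them. Transthyretin (Ttr), the main transcript of the choroid plexus, ranged from 26.65 CPM in SUMO-KO 3 to 4721 CPM in Q175HD_SUMO-KO 1, with high and low libraries in every genotype. Slc17a7, the vesicular glutamate transporter of cortical neurons, was at 384.5, 244.8 and 106.4 CPM in the WT libraries and between 12.89 and 106.4 CPM in the other 9. The collagen gene Col1a1 reached 82.83 CPM in Q175HD_SUMO-KO 1 and lay between 4.775 and 11.49 CPM elsewhere.

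Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534, GRCm38) was at 268 ± 17.8 CPM in WT, 276 ± 22.5 in SUMO-KO, 197 ± 8.37 in Q175HD and 189 ± 29.5 in Q175HD_SUMO-KO (SD, n = 3 each). Htt fell with the knock-in by 0.44 (SE 0.11, adjusted p = 0.0429 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) with SUMO-1 present and by 0.55 (SE 0.11, edgeR adjusted p = 0.00926) without it, on the log2 scale. The first of these edgeR calls was lost without any 1 of its 6 libraries, with an adjusted p of at most 0.172 without Q175HD 3.

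**Figure D1:**
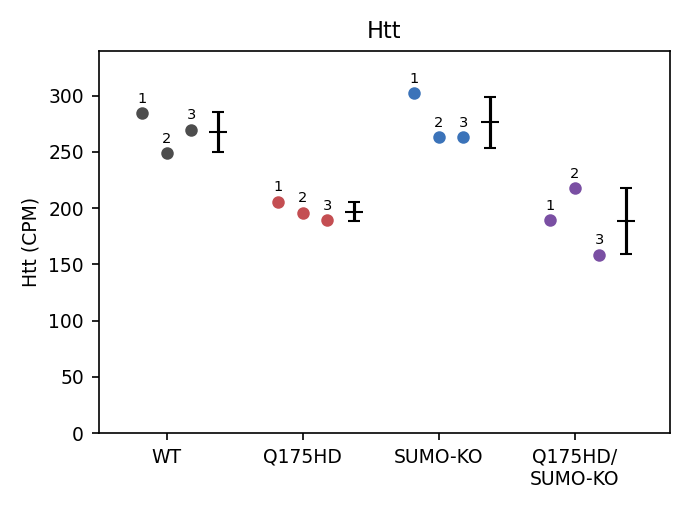
CPM of Htt in each of the 12 libraries, numbered by replicate, with the mean and SD of each genotype as a black bar. Htt lies at or below 217.7 CPM in the 6 knock-in libraries and at or above 249.1 CPM in the other 6.

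The first comparison, Q175HD against WT, asks what the Htt knock-in changes while SUMO-1 is present. Genes that mark the medium spiny projection neurons of the striatum fell: Ryr1, an intracellular calcium release channel, from 117 ± 4.42 to 16.5 ± 0.222 CPM (SD, n = 3 each), the cannabinoid receptor Cnr1 from 432 ± 3.21 to 153 ± 7.53 CPM, and the enkephalin precursor Penk from 720 ± 102 to 295 ± 31.7 CPM. Some transcription factors of the embryo that the adult striatum hardly expresses rose, with Lmx1b going from 0.112 ± 0.0967 to 13 ± 2.36 CPM and Onecut1 from 0 reads in the WT libraries to 4.14 ± 0.541 CPM. Some genes of cortical neurons were also lower in Q175HD, and these varied widely among the WT libraries. The mean of the cortical list differed by -1.09 on the log2 scale (exact permutation p = 0.2, two-sided, n = 3 each). In all, 198 genes rose and 501 fell at an edgeR adjusted p under 0.05, and 3170 had an unadjusted p under 0.05.

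Of 42 tested genes of the striatal projection neuron list, 19 fell and 0 rose by the edgeR test (31 fell when adjusted over the list alone), and 2 of 42 had a positive log2 fold change. The fold changes were -2.83 for Ryr1 (SE 0.14, edgeR adjusted p = 3.47e-07), -1.67 for the sodium channel subunit Scn4b (SE 0.36), -1.5 for Cnr1 (SE 0.16, edgeR adjusted p = 0.000328) and -1.29 for Penk (SE 0.17). The list ranked low among all genes (camera adjusted p = 3.37e-36), which was lost with an estimated correlation (adjusted p = 0.0656). The list's mean per library differed by -0.64 on the log2 scale (exact permutation p = 0.1, the smallest possible, two-sided, n = 3 each). Markers of both projection pathways were among the falls. In the indirect pathway list 5 of 8 genes fell (6 adjusted over the list alone), including the receptors Gpr6 (-0.81, SE 0.14) and Drd2 (-0.74, SE 0.18), and the list held with an estimated correlation (adjusted p = 0.026). In the direct pathway list 2 of 9 fell (4 fell and 1 rose adjusted over the list alone), the receptors Chrm4 (-0.8, SE 0.13) and Drd1 (-0.72, SE 0.14), with a camera adjusted p of 0.0224 and 0.387 with an estimated correlation. Each pathway list shares 6 genes with the projection neuron list. Rasd2 (ENSMUSG00000034472, chromosome 8, 75213944 to 75224113), a striatal GTPase known as Rhes that binds huntingtin, was at 405 ± 14 against 608 ± 93.5 CPM, which did not pass (edgeR adjusted p = 0.281).

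Receptors for glutamate and GABA fell as a group: 12 of 36 fell and 0 rose (18 fell adjusted over the list alone), and the list held with an estimated correlation (camera adjusted p = 1.41e-13, and p = 0.014 with the estimate). The GABA-A receptor subunit Gabra2 fell from 127 ± 26.7 to 45.5 ± 5.27 CPM, a log2 fold change of -1.48 (SE 0.19, edgeR adjusted p = 0.00117), and the kainate receptor subunits Grik3 (-0.71, SE 0.13) and Grik2 (-0.64, SE 0.14) and the GABA-B receptor Gabbr2 (-1.02, SE 0.22) also fell. Gabra2 was not low in the knock-in without SUMO-1, with a log2 fold change of -0.05 (SE 0.18) in Q175HD_SUMO-KO against WT. Of 23 immediate early genes, which neurons induce on activity, 4 fell and 0 rose (9 adjusted over the list alone): Homer1 (-0.99, SE 0.19), Nr4a3 (-0.73, SE 0.18), Sik1 (-0.67, SE 0.15) and Dusp1 (-0.64, SE 0.16). The list was low by camera (median -0.55, adjusted p = 6.78e-08), not with an estimated correlation (adjusted p = 0.197). It was also low in SUMO-KO against WT (median -0.42, 4 fell adjusted over the list alone, camera adjusted p = 3.4e-06, and adjusted p = 0.489 with an estimated correlation). The list means in WT 1, 2 and 3 were 0.27, 0.005 and -0.275, and those of cortical neuron genes were 0.688, 0.065 and -0.753. Without WT 1 and WT 2 the immediate early medians were -0.36 in Q175HD against WT and -0.25 in SUMO-KO against WT, and with the cortical list mean as a covariate they were -0.56 and -0.46.

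Of 21 tested homeobox and other developmental transcription factors, 6 rose and 0 fell (8 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 6.78e-08 and an adjusted p of 0.0162 with an estimated correlation. Of the 59 factors listed only these 21 passed the filter on reads, and 12 of them had a positive log2 fold change (median 0.32). The 6 rises were among 8 members with under 10 reads in every WT library, and a gene passes the filter by its reads in any genotype. The list's p is therefore not independent of that filter. With no filter 7 of 54 factors rose and 0 fell by edgeR, and a mean count of at least 50 left 6, with a median of -0.06 and 0 calls by edgeR. Onecut1 was at least 51.4-fold higher, Hoxc8 at least 15.4-fold and Hoxd8 at least 5.85-fold, each against a floor of 3 counts over the WT group, which had 0 reads. Floors cover counting error only. Pax2 rose from 0.0248 ± 0.043 to 1.66 ± 0.388 CPM. Outside the list, the largest rises under the rule for named genes were Lmx1b (log2 fold change 6.79, SE 0.4, edgeR adjusted p = 1.41e-06), the homeobox gene Shox2 (3.2, SE 0.7), the Polycomb-associated gene Sfmbt2 (2.35, SE 0.21), the ion channel relative Tmc3 (2.22, SE 0.25), the troponin Tnnt2 (1.77, SE 0.3) and the Polycomb gene Cbx8 (1.28, SE 0.11). Emx2os, which lies antisense to Emx2, rose by 1.74 (SE 0.2), but the counting strand is not stated and its reads cannot be told from those of its partner. Among the 22 beta protocadherins, cell adhesion genes of 1 cluster whose similar sequences can share reads, 7 rose and 0 fell (13 adjusted over the list alone), such as Pcdhb9 (0.76, SE 0.13) and Pcdhb22 (0.73, SE 0.16). Their camera adjusted p was 3.08e-09, and the adjusted p with an estimated correlation was 0.32.

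Among the steepest falls were genes of the deep cortical layers, Ctgf (-3.86, SE 0.48), Cplx3 (-3.35, SE 0.37) and Nxph3 (-2.88, SE 0.48), and the neuronal pentraxin Nptx1 (-2.78, SE 0.53). In the cortical excitatory neuron list 3 of 20 fell and 0 rose (9 adjusted over the list alone), namely Nptx1, Emx1 (-2.01, SE 0.49) and Fezf2 (-1.55, SE 0.4), with a camera adjusted p of 1.02e-05 and an adjusted p of 0.372 with an estimated correlation. The mean of this list in WT 1, WT 2 and WT 3 was 0.688, 0.065 and -0.753 around the WT mean on the log2 scale. The same WT libraries enter the falls of the projection neuron and receptor genes, whose medians were -0.59 and -0.44. Without WT 1 and WT 2, chosen after their cortical values were seen, 68 genes passed in all and the median of the projection neuron list was -0.71. The falls called then numbered 5 in the projection neuron list and 1 in the receptor list, and 1 developmental factor rose. The cortical median was -0.19, a decrease that follows from the choice of these libraries.

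The SUMO conjugation list had 2 rises among 27 genes (3 adjusted over the list alone), among them Sumo2 (0.46, SE 0.12), with a camera adjusted p of 0.0175 and an adjusted p of 0.293 with an estimated correlation. In the cytokine and innate inflammation list 2 of 27 rose (2 adjusted over the list alone), the complement gene C4b (0.87, SE 0.18) and the transcription factor Relb (0.87, SE 0.21), with a camera adjusted p of 0.026 and an adjusted p of 0.372 with an estimated correlation. Of 25 cholesterol synthesis genes 1 fell, Insig1 (-0.6, SE 0.11), and 9 fell adjusted over the list alone. Their camera adjusted p was 0.000165, and the adjusted p with an estimated correlation was 0.372. Of 22 astrocyte genes, Vim rose (0.59, SE 0.13) and Mfge8 fell (-0.58, SE 0.14), and 1 of each was called when adjusted over the list alone. The camera adjusted p of this list was 0.305 by limma. The newly formed oligodendrocyte gene Enpp6 rose (0.87, SE 0.18), alone among 12 oligodendrocyte precursor genes (1 adjusted over the list alone), with a limma camera adjusted p of 0.138. Of 16 striatal interneuron genes, the potassium channel Kcnc2 (-1.08, SE 0.27) and the neuropeptide Npy (-0.56, SE 0.12) fell (3 adjusted over the list alone). Their camera adjusted p was 0.00285, and the adjusted p with an estimated correlation was 0.387.

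No gene of the remaining lists passed by edgeR over all genes. Of these the interferon response (35 genes, median log2 fold change 0.65), microglia (27, 0.13), lysosome (36, 0.12), cytosolic ribosomal protein (78, 0.14) and nuclear-encoded oxidative phosphorylation (80, 0.08) lists leaned upward by camera, with adjusted p of 5.93e-07, 0.0212, 0.00254, 1.49e-06 and 0.0329, and none did with an estimated correlation (adjusted p of 0.467, 0.605, 0.463, 0.599 and 0.854). The interferon list mean was 1.214 in Q175HD 2 against 0.244 and 0.16 in Q175HD 1 and 3, and 0.293 in WT 2, and the median log2 fold change was 0.2 without Q175HD 2. The autophagy (43 genes), heat shock (30), mitochondrially encoded (10), myelinating oligodendrocyte (22), endothelial and pericyte (21), choroid plexus (18), ependymal (12), thalamic, septal and pallidal neuron (16), meningeal fibroblast (15) and blood (5) lists were not called. In the same order their camera adjusted p lay at 0.337, 0.639, 0.513, 0.813, 0.0948, 0.466, 0.0948, 0.0517, 0.592 and 0.513. Adjusted over the list alone, 2 thalamic, septal and pallidal genes fell and the other lists of this group had 0.

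The number of calls was lower with any single library left out: it was 297 without WT 1, 272 without WT 2 and 593 without WT 3. It was 226 without Q175HD 1, 242 without Q175HD 2 and 210 without Q175HD 3. Having fewer libraries was not separated here from the influence of particular ones. Of 61 called genes named by the rule, 24 passed whichever single library was left out, among them Lmx1b, Sfmbt2, Cbx8, Ryr1, Cnr1, Penk, Onecut1 and Gabra2. The other 37 lost the call in at least 1 such edgeR fit. They included Scn4b (adjusted p of at most 0.113, without Q175HD 3), Drd2 (0.145, without Q175HD 2), Drd1 (0.0754, without Q175HD 2), Sumo2 (0.159, without WT 1), the developmental genes Shox2 (0.136, without WT 1), Hoxc8 (0.0682, without Q175HD 3) and Hoxd8 (0.0537, without Q175HD 3), and Relb (0.166, without Q175HD 3).

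**Figure D2:**
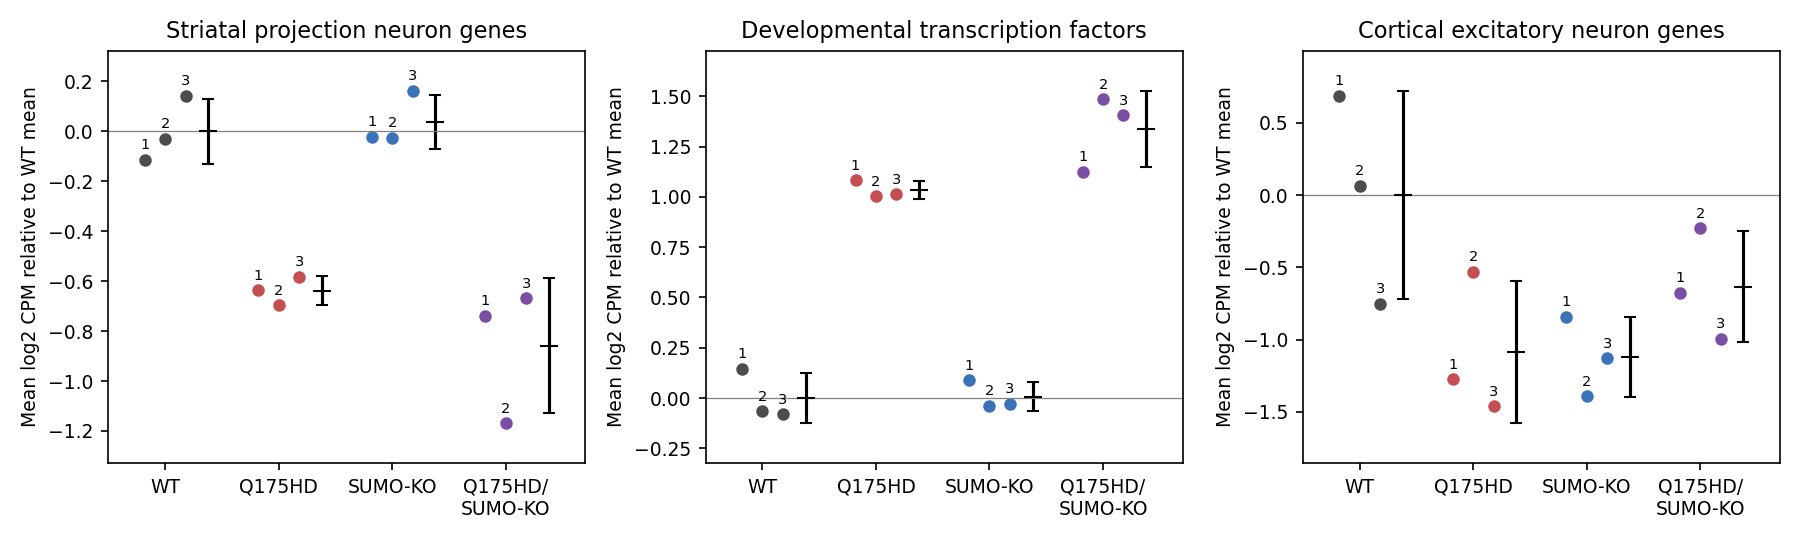
Mean log2 CPM over the tested genes of 3 lists, relative to the WT mean of each gene, in each library (points numbered by replicate; black bars give mean and SD). The projection neuron mean lies between -1.169 and -0.582 in the 6 knock-in libraries, and the cortical mean ranges from -0.753 to 0.688 among the WT libraries.

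Q175HD_SUMO-KO against SUMO-KO gives the effect of the same knock-in without SUMO-1. Projection neuron genes fell, with Ryr1 going from 150 ± 29.9 to 14.8 ± 2.3 CPM, the phosphodiesterase Pde10a from 2190 ± 48.7 to 641 ± 154 CPM and the dopamine receptor Drd1 from 336 ± 17.1 to 157 ± 30.6 CPM (SD, n = 3 each). Some developmental transcription factors rose, with Hoxc5 and Hoxc4 from 0 reads to 11.3 ± 5.2 and 11.1 ± 3.46 CPM and Wt1 from 0.102 ± 0.0998 to 8.14 ± 1.7 CPM. Gpx6, a glutathione peroxidase, fell from 9.52 ± 4.22 to 0.243 ± 0.0767 CPM. By edgeR, 568 genes rose and 821 fell at an adjusted p under 0.05, with 4340 at an unadjusted p under 0.05.

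Of 42 projection neuron genes, 32 fell and 0 rose (37 adjusted over the list alone), and the list was low both by camera (adjusted p = 3.05e-51) and with an estimated correlation (adjusted p = 0.0234). The log2 fold changes were -3.34 for Ryr1 (SE 0.14, edgeR adjusted p = 5.23e-08), -2.07 for Scn4b (SE 0.36), -1.77 for Pde10a (SE 0.15, edgeR adjusted p = 2.11e-05) and -1.56 for Cnr1 (SE 0.16). The list mean differed by -0.9 (exact permutation p = 0.1, two-sided, n = 3 each). In the direct pathway list 3 of 9 fell (5 adjusted over the list alone): Drd1 (-1.1, SE 0.14), the dynorphin precursor Pdyn (-1.02, SE 0.25) and Chrm4 (-0.84, SE 0.14), with an adjusted p of 0.203 with an estimated correlation. In the indirect pathway list 5 of 8 fell (5 adjusted over the list alone), including the adenosine receptor Adora2a (-1.32, SE 0.24), Gpr6 (-1.21, SE 0.14) and Penk (-1.17, SE 0.17), and this list held with an estimated correlation (adjusted p = 0.0234). Rasd2 fell by 1 on the log2 scale, from 558 ± 99.7 to 279 ± 116 CPM (SE 0.27, edgeR adjusted p = 0.0456). It was at 145.2 CPM in Q175HD_SUMO-KO 2 against 340.1 and 353.2 in the other 2, and its call was lost in 4 of 6 fits without 1 library (adjusted p at most 0.102, without SUMO-KO 3).

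Among 36 glutamate and GABA receptor genes 13 fell and 0 rose (16 fell and 1 rose adjusted over the list alone), among them the metabotropic receptors Grm7 (-0.85, SE 0.15) and Grm4 (-0.79, SE 0.12) and the GABA-A subunit Gabrd (-0.93, SE 0.13), and the list held with an estimated correlation (adjusted p = 0.0234). Of 21 developmental transcription factors 8 rose and 0 fell (8 rose and 1 fell adjusted over the list alone, adjusted p = 0.0234 with an estimated correlation), with a median of 0.46. Of these rises 7 were among 9 members with under 10 reads in every SUMO-KO library, so this p too is not independent of the filter. With no filter 9 of 54 rose and 0 fell by edgeR. With a mean count of at least 50 the 6 factors left had a median of -0.13, and 0 rose and 1 fell. Hoxd8 was at least 32.9-fold and Pax2 at least 28.7-fold higher, and outside the list Hoxc5 was at least 126-fold and Hoxc4 at least 124-fold higher, against a floor of 3 counts over the SUMO-KO group. Hoxc4 and Hoxc5 are neighbours with overlapping transcripts, so reads of one can be counted for the other. Lmx1b rose by 6.05 (SE 0.38, edgeR adjusted p = 3.28e-06), Shox2 by 4.23 (SE 0.76) and Sfmbt2 by 2.69 (SE 0.21). Other steep falls were Gpx6 (-5.22, SE 0.47), the lipid-transfer gene Sec14l3 (-3.32, SE 0.43), the endopeptidase Phex (-2.85, SE 0.33), Abi3bp (-2.67, SE 0.21) and the orphan receptor Gpr139 (-2.52, SE 0.37). Of 22 beta protocadherins 7 rose (10 adjusted over the list alone, adjusted p = 0.517 with an estimated correlation), Pcdhb2 the most (1.03, SE 0.21).

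Of 78 cytosolic ribosomal protein genes, which have many near-identical pseudogene copies, 14 rose and 0 fell (50 adjusted over the list alone), such as Rpl7a (0.45, SE 0.09) and Rpl11 (0.46, SE 0.11), with a camera adjusted p of 7.34e-17 and 0.509 with an estimated correlation. Across genes, the deviation of a library from the mean of all libraries correlated with log2 transcript length at 0.267, 0.142 and 0.041 in SUMO-KO 1, 2 and 3 and at -0.092, 0.012 and -0.271 in Q175HD_SUMO-KO. With the GC and length trends removed, a setting added after seeing the data, 12 ribosomal protein genes rose and the median was 0.26 against 0.29. Of 23 immediate early genes 1 fell (1 adjusted over the list alone), with a median of 0.1 and a limma camera adjusted p of 0.513. Of 80 nuclear-encoded oxidative phosphorylation genes 6 rose (6 adjusted over the list alone), such as Ndufb6 (0.51, SE 0.12) and Atp5g1 (0.5, SE 0.11), with an estimated-correlation adjusted p of 0.613. Among SUMO conjugation genes 2 rose, including Sumo2 (0.49, SE 0.12) (2 adjusted over the list alone). In the astrocyte list Vim rose (0.82, SE 0.13), and the bicarbonate transporter Slc4a4 (-0.75, SE 0.13), the glutamate transporter Slc1a2 (-0.47, SE 0.11) and Mfge8 (-0.53, SE 0.14) fell (2 rose and 5 fell adjusted over the list alone). Among 43 autophagy genes, Atg5 and Wdr45b rose by 0.31 each (SE 0.09 and 0.08), and Epg5 (-0.35, SE 0.09) and Pik3r4 (-0.29, SE 0.08) fell (3 each way adjusted over the list alone). Further rises were the cytokine-list genes Serpina3n (0.91, SE 0.2) and Relb (0.91, SE 0.22), the lysosomal protease Ctsl (0.62, SE 0.13) and the chaperone Dnajb1 (0.57, SE 0.14), and falls were the cholesterol genes Cyp46a1 (-0.52, SE 0.14) and Insig1 (-0.51, SE 0.11). Adjusted over the list alone, 4 cytokine-list genes rose, 2 lysosomal genes rose and 1 fell, 1 chaperone rose and 3 cholesterol genes fell. Camera also called the cytokine (adjusted p = 0.00478), lysosome (0.00019), interferon (0.000161) and interneuron (0.00896) lists, but their adjusted p values with an estimated correlation were 0.287, 0.509, 0.699 and 0.517. In the cortical list Rprm (2.29, SE 0.35) and Nrn1 (2.13, SE 0.33) rose (2 adjusted over the list alone), with a camera adjusted p of 0.0275 and an adjusted p of 0.708 with an estimated correlation. Its median was 0.34, and -0.02 without Q175HD_SUMO-KO 2. The list means of cortical genes in SUMO-KO 1, 2 and 3 were -0.842, -1.391 and -1.131 around the WT mean, and -0.676, -0.231 and -0.993 in Q175HD_SUMO-KO.

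The count of calls was 847 without SUMO-KO 1, 2395 without SUMO-KO 3, 747 without Q175HD_SUMO-KO 1 and 821 without Q175HD_SUMO-KO 3, and 407 when only the 6 libraries were fitted. Of 74 called genes named by the rule, 48 passed whichever single library was left out. Among the 26 that did not, by edgeR, were Pdyn (adjusted p at most 0.12, without Q175HD_SUMO-KO 3), Atg5 (0.221, without Q175HD_SUMO-KO 3), Pik3r4 (0.118, without Q175HD_SUMO-KO 2), Sumo2 (0.0852, without SUMO-KO 2) and Rpl7a (0.0609, without Q175HD_SUMO-KO 3).

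The knock-in effects with and without SUMO-1 were set side by side, since the comparisons share no library. Across the 17796 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.597 and a Spearman rho of 0.573 (covariance 0.16). The rises shared 129 genes, where independent lists of these sizes would share 6.32, and the falls shared 322, against 23.1, with 1 gene called in opposite directions. For 3001 genes called for the knock-in effect averaged over SUMO-1 status, the effect was larger without SUMO-1 by a median of 0.0944 on the log2 scale (limma fry p = 0.0333, two-sided rotation test, n = 12 libraries). Of these genes 68% leaned that way. Genes lower with the knock-in had a median log2 fold change of -0.5 with SUMO-1 and -0.56 without it, and genes higher with the knock-in had 0.32 and 0.4. The fry p of this size difference, by limma, was 0.0643 without WT 2, 0.607 without WT 3, 0.0743 without Q175HD 1, 0.112 without Q175HD 2 and 0.0531 without Q175HD_SUMO-KO 2, and it passed without any other 1 library.

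**Figure D3:**
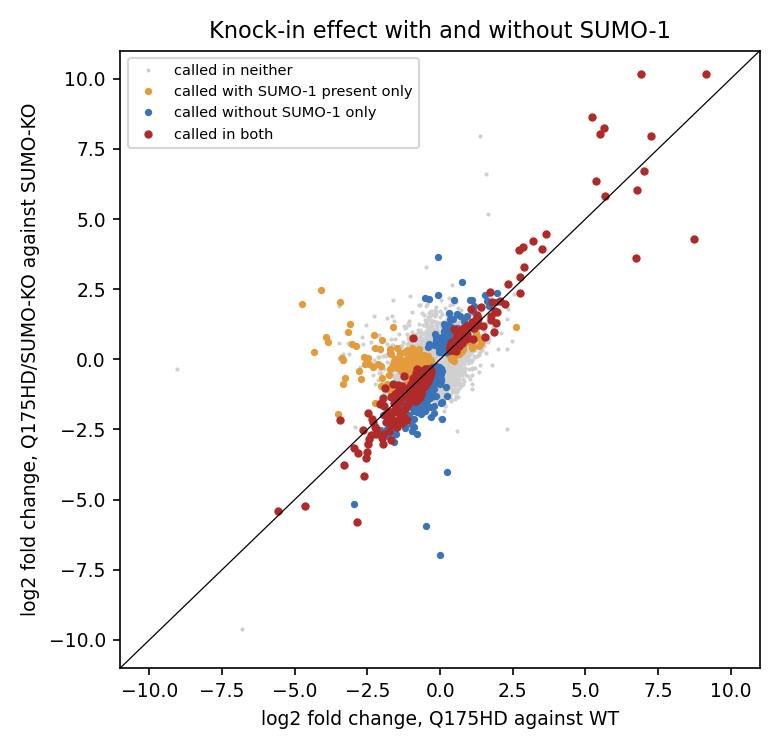
Log2 fold change of each tested gene in Q175HD against WT (x axis) and in Q175HD_SUMO-KO against SUMO-KO (y axis), coloured by the comparison in which edgeR called it, with the line of equal change. The 129 shared rises and 322 shared falls lie in the upper right and lower left.

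SUMO-KO against WT asks what the loss of SUMO-1 changes without the knock-in. Few genes were called by edgeR: the maternally expressed noncoding RNA Rian rose from 529 ± 55 to 905 ± 78.6 CPM, and the deep-layer cortical genes Ctgf and Cplx3 fell from 33 ± 16.7 to 2.23 ± 1.15 and from 14.7 ± 5.91 to 1.35 ± 0.583 CPM (SD, n = 3 each). The immunoglobulin heavy chain gene Ighm fell from 22.7 ± 7.51 to 7.23 ± 1.57 CPM. By edgeR, 2 genes rose and 6 fell, with 2395 at an unadjusted p under 0.05, while DESeq2 called 250 and limma voom with sample quality weights 349. The low edgeR count therefore does not show that few genes changed. The log2 fold changes were 0.78 for Rian (SE 0.12, edgeR adjusted p = 0.0371), -3.84 for Ctgf (SE 0.48), -3.42 for Cplx3 (SE 0.38) and -1.64 for Ighm (SE 0.25). Of 42 projection neuron genes 0 were called over all genes (1 rise and 1 fall adjusted over the list alone), and Htt and Rasd2 did not pass (edgeR adjusted p of 0.882 and 0.864). By camera 10 of 29 lists were called, led by cortical excitatory neuron genes (median -1.35, 12 of 20 down adjusted over the list alone, camera adjusted p = 2.2e-12) and cholesterol synthesis genes (median -0.23, 10 of 25 down adjusted over the list alone, camera adjusted p = 1.7e-10), and none held with an estimated correlation (lowest adjusted p = 0.353). Beside the cholesterol genes, myelinating oligodendrocyte genes had a median of -0.22 with 0 of 22 positive and 0 called (0 adjusted over the list alone, camera adjusted p = 0.000231, and adjusted p = 0.847 with an estimated correlation). Cortical genes were highest in WT 1 and WT 2, with list means of 0.688 and 0.065. Calls numbered 1422 without SUMO-KO 3, 137 without WT 3, 0 without WT 2, 1 without SUMO-KO 2, 3 without WT 1 and 4 without SUMO-KO 1. Every call named here was lost in at least 1 of those edgeR fits. SUMO-KO 1 and 2, which remain without SUMO-KO 3, had the fewest reads of all libraries (9379594 and 10120161). The first principal component of log2 CPM was at 64.7 and 50.2 in them and at -6.3 in SUMO-KO 3. It was at -7.7, 20.8 and -3.6 in WT 1, 2 and 3, so the 1422 calls cannot be ascribed to genotype alone. Cplx3 was lost only without WT 2 (edgeR adjusted p = 0.0573), Rian with an adjusted p up to 0.267 without WT 1, Ctgf up to 0.231 without SUMO-KO 2 and Ighm up to 0.256 without SUMO-KO 1. Rian and Ighm were also not called with the replicate number as a block.

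Q175HD_SUMO-KO against Q175HD asks what the loss of SUMO-1 changes in the knock-in, the question in the title of the series. Gabra2 rose from 45.5 ± 5.27 to 123 ± 25.7 CPM, the nuclear receptor and immediate early gene Nr4a3 from 13.6 ± 2.7 to 34.8 ± 2.54 CPM, and Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, from 25.8 ± 1.81 to 40 ± 2.1 CPM (SD, n = 3 each). Gabra2 lay between 39.42 and 48.76 CPM in the Q175HD libraries and between 100.8 and 170.9 CPM in the other 9. For Gabra2 and Nnt, a strain background of the Q175HD animals could not be told apart from an effect of SUMO-1 loss, as described under other observations. By edgeR over all genes no projection neuron gene, developmental transcription factor or inflammation gene was called, and adjusted over the list alone 1 developmental factor rose. By edgeR 4 genes rose and 2 fell, with 939 at an unadjusted p under 0.05, and DESeq2 called 19. The log2 fold changes were 1.43 for Gabra2 (SE 0.19, edgeR adjusted p = 0.0187), 1.35 for Nr4a3 (SE 0.18, edgeR adjusted p = 0.0178) and 0.63 for Nnt (SE 0.09, edgeR adjusted p = 0.0258). Htt and Rasd2 did not pass (edgeR adjusted p of 0.944 and 0.903). By camera 18 of 29 lists were called, among them myelinating oligodendrocyte genes (0 of 22 positive, median -0.37, camera adjusted p = 1.31e-16), ribosomal proteins (median 0.16, 8.6e-14), projection neuron genes (median -0.16, 3.94e-11) and interferon response genes (median -0.38, 2.07e-08), and none held with an estimated correlation (lowest adjusted p = 0.436). The interferon median was 0.01 without Q175HD 2, the library with the highest mean of that list (1.214). The projection neuron list means were -0.739, -1.169 and -0.668 in Q175HD_SUMO-KO 1, 2 and 3 and -0.635, -0.697 and -0.582 in Q175HD. Q175HD_SUMO-KO 2, the lowest, was the only knock-in library with abundant Xist, and in male libraries only the projection neuron median was -0.09. Counts of calls were 1 without Q175HD 1, Q175HD 2 or Q175HD_SUMO-KO 1, 2 without Q175HD 3 and 3 without Q175HD_SUMO-KO 2. By edgeR Nnt was lost without any 1 of the 6 (adjusted p up to 0.262 without Q175HD 2), Gabra2 in 5 of 6 fits (up to 0.173 without Q175HD 2) and Nr4a3 in 3 (up to 0.141 without Q175HD 2).

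Across genes the effects of SUMO-1 loss with and without the knock-in, which share no library, correlated with a Pearson r of 0.336 and a Spearman rho of 0.377 (covariance 0.0529), and the calls shared 1 rise and 1 fall. Among genes starting within 10 Mb of Htt, 7 of 191 were called in Q175HD against WT and 16 of 191 in Q175HD_SUMO-KO against SUMO-KO, which did not differ from the rest (two-sided Fisher's exact p of 1 and 0.685, Htt itself left out).

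In Q175HD_SUMO-KO against WT, where both changes meet, 599 genes rose and 903 fell by edgeR. The developmental genes Hoxc4 (at least 138-fold higher, against a floor of 3 counts over the WT group), Lmx1b (6.74, SE 0.4) and Wt1 (5.82, SE 0.45) rose, the synaptic gene Slitrk6 (1.73, SE 0.36) and the receptor Gpr101 (1.63, SE 0.37) rose, and Ryr1 (-2.99, SE 0.14), Scn4b (-2.3, SE 0.37), Ptpn7 (-2.77, SE 0.31) and Cpne9 (-2.38, SE 0.25) fell. Of 42 projection neuron genes 29 fell (35 fell and 1 rose adjusted over the list alone), with an adjusted p of 0.0297 with an estimated correlation, and Rasd2 fell by 1.12 (SE 0.27, edgeR adjusted p = 0.0278). Of 25 cholesterol synthesis genes 8 fell (10 adjusted over the list alone), with a camera adjusted p of 6.18e-07 and 0.289 with an estimated correlation. Myelinating oligodendrocyte genes (4 of 22 fell, 7 adjusted over the list alone, median -0.42) and astrocyte genes (4 of 22 fell and 1 rose, 7 and 1 adjusted over the list alone, median -0.29) were low as well. Their camera adjusted p values were 2.51e-06 and 0.00217, and with an estimated correlation the adjusted p values were 0.46 and 0.502. The cortical list mean of WT libraries bears on this comparison as well, and calls numbered 190 without WT 1 and WT 2, 682 without WT 1, 767 without WT 2, 674 without Q175HD_SUMO-KO 1 and 914 without Q175HD_SUMO-KO 3. Of 88 called genes named by the rule, 46 passed whichever single library was left out. By edgeR Rasd2 was lost without WT 1, WT 2 or WT 3 (adjusted p up to 0.0765, without WT 3), Gpr101 in 4 of 6 fits (up to 0.0808, without WT 2) and Slitrk6 without WT 2 (0.055).

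Q175HD against SUMO-KO sets the single changes against each other, and 624 genes rose and 970 fell by edgeR. Interferon response genes were called here, with 12 of 35 rising and 0 falling (20 adjusted over the list alone), such as Ifit3b (1.63, SE 0.35), and 6 of 36 lysosomal genes rose (21 rose and 1 fell adjusted over the list alone). Their camera adjusted p values were 3.52e-11 and 5.59e-08, and with an estimated correlation the adjusted p values were 0.441 and 0.201. Interferon list means were 0.244, 1.214 and 0.16 in Q175HD 1, 2 and 3 and -0.546, -0.129 and -0.24 in SUMO-KO. Without Q175HD 2 the interferon list had a median of 0.48, against 0.87 with it, and 0 of its genes passed by edgeR, Ifit3b with an adjusted p of 0.063. Of 42 projection neuron genes 25 fell (32 adjusted over the list alone, adjusted p = 0.114 with an estimated correlation), and the iodide transporter Slc5a5 rose (1.79, SE 0.21) while Gpx6 fell (-5.02, SE 0.45). Calls numbered 3933 without SUMO-KO 3, 475 without Q175HD 2, 654 without Q175HD 1, 666 without Q175HD 3, 666 without SUMO-KO 1 and 759 without SUMO-KO 2. Of 83 called genes named by the rule, 44 passed whichever single library was left out.

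The interaction asks whether the effect of one change differs with the other. By edgeR 0 genes passed, with 770 at an unadjusted p under 0.05, and limma voom also called 0 while DESeq2 called 31. Htt and Rasd2 had interaction log2 fold changes of -0.11 (SE 0.16) and -0.41 (SE 0.38), each with an edgeR adjusted p of 0.997. By camera 12 of 29 lists were called and none with an estimated correlation (lowest adjusted p = 0.116). Immediate early genes had a median of 0.51 with 23 of 23 positive (2 rose adjusted over the list alone), and cortical excitatory neuron genes a median of 1.95 (10 rose adjusted over the list alone). Without WT 3 the interaction had 34 calls, without SUMO-KO 1 it had 2 and without WT 2 it had 1.

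The authors' deposited table of Q175HD against WT holds 1042 genes at an adjusted p under 0.05, of which 690 are among the 699 calls made here. For SUMO-KO against WT, Q175HD_SUMO-KO against Q175HD and Q175HD_SUMO-KO against SUMO-KO, the authors' deposited table holds 245, 19 and 1715, with 7 of 8, 6 of 6 and 1354 of 1389 calls shared.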

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

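All tests of explanations in this part were chosen only after the results were seen, while the list tests and the size comparison were planned. The interaction asks whether the effect of the knock-in differs with SUMO-1 status, and the results below are those where that difference passed its planned test. With camera's preset correlation they were the lists of striatal projection neuron genes (adjusted p = 4.48e-09, median interaction -0.22), direct pathway genes (0.0116, median -0.14), immediate early genes (3.45e-14, median 0.51), heat shock and chaperone genes (0.00234, median 0.22), cholesterol synthesis genes (8.23e-05, median 0.14), oxidative phosphorylation genes (1.02e-07, median 0.14), ribosomal proteins (1.98e-08, median 0.14), myelinating oligodendrocyte genes (0.0357, median -0.16), oligodendrocyte precursor genes (0.00766, median -0.22), endothelial and pericyte genes (0.0097, median 0.22), choroid plexus genes (0.0029, median 1.69) and cortical excitatory neuron genes (4.73e-19, median 1.95). With an estimated correlation none of the 12 passed, and the lowest adjusted p was 0.116. With the cortical list mean as a covariate the medians of projection neuron and direct pathway genes were 0.11 each, of the other sign, and without WT 1 and WT 2 they were -0.07 and -0.06. In the latter fit the choroid plexus median was -2.54 and the heat shock median 0.01. Immediate early genes had medians of 0.7 and 0.49 in these fits. The size of the knock-in effect also differed with SUMO-1 status (limma fry p = 0.0333, two-sided rotation test, n = 12 libraries), with larger effects without SUMO-1 by a median of 0.0944. It did not pass without WT 2, WT 3, Q175HD 1, Q175HD 2 or Q175HD_SUMO-KO 2, with a limma fry p of up to 0.607 without WT 3. By edgeR 0 single genes passed the interaction, 770 had an unadjusted p under 0.05, and DESeq2 called 31.

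Cortical excitatory neuron genes had medians of -1.17 in Q175HD against WT and -1.35 in SUMO-KO against WT, with 3 and 0 of 20 genes called by edgeR (9 and 12 adjusted over the list alone), adjusted p of 0.372 and 0.353 with an estimated correlation, and exact permutation p of 0.2 and 0.1 for the list mean. Among the 9 other libraries the 20 members varied together within a genotype, with a mean correlation of 0.2 against a median of -0.01 in 10000 random lists of like expression (p = 0.0018, one-sided permutation test), and 3 of the 9 had a list mean above that of WT 3. With the trends of GC content and transcript length removed the median in Q175HD against WT was -1.07, which argues against those trends. Differing amounts of cortical tissue between libraries may therefore account for part of the difference in these genes and for part of their interaction, while a change of cortical transcripts in the striatum was not tested and stays open. Ctgf and Cplx3 did not follow Slc17a7: WT 3 and Q175HD_SUMO-KO 2 both had 106.4 CPM of Slc17a7, but 8.047 and 0.5895 CPM of Cplx3 and 16.91 and 5.305 CPM of Ctgf, and what lowers these 2 genes outside WT is left open.

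Striatal projection neuron genes were lower with the knock-in, and cortical tissue in WT libraries would lower their share in WT, not raise it. Where no WT library is used, in Q175HD_SUMO-KO against SUMO-KO, their median was -0.75 and the list passed camera with an estimated correlation (adjusted p = 0.0234). That is no test of cortical tissue in WT libraries, which could not give a fall. The cortical median there was 0.34, so cortical tissue may differ in this comparison too. With the cortical list mean as a covariate, the projection neuron medians were -0.64 there and -0.87 in Q175HD against WT. With the GC and length trends removed the projection neuron median in Q175HD_SUMO-KO against SUMO-KO was -0.76, which argues against these trends. A response to the knock-in, which the design names, is consistent with these values and stays a hypothesis, and a loss of these neurons was not separated from lower transcription in them.

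Regroupings of the 6 libraries of a comparison number 10, too few for a share under 0.05. As many calls as the real grouping came from 1 split, the real one, in Q175HD against WT (699, highest other 0), SUMO-KO against WT (8, highest other 0), Q175HD_SUMO-KO against Q175HD (6, highest other 0), Q175HD_SUMO-KO against WT (1502, highest other 1) and Q175HD against SUMO-KO (1594, highest other 0). In Q175HD_SUMO-KO against SUMO-KO 2 splits gave as many, the real one with 1389 and the split of SUMO-KO 1, SUMO-KO 2 and Q175HD_SUMO-KO 2 from the other 3 with 1496. For the interaction the real count was 0, so 100 of 100 splits gave at least as many by construction, which says nothing about chance. The highest gave 1410, with WT 1, WT 3, SUMO-KO 3, Q175HD 1, Q175HD_SUMO-KO 1 and Q175HD_SUMO-KO 2 on 1 side, and 98 of the others gave 0. The splits with 1496 and 1410 calls point to a structure of the samples apart from genotype. The first principal component of log2 CPM held 34.8% of the variance. It was at 64.7, 50.2 and 20.6 in SUMO-KO 1, SUMO-KO 2 and Q175HD_SUMO-KO 2. In SUMO-KO 3, Q175HD_SUMO-KO 1 and Q175HD_SUMO-KO 3 it was at -6.3, -7.8 and -48. The former 3 libraries had the fewest reads of the 12, from 9379594 to 11237097. Among them SUMO-KO 2 and Q175HD_SUMO-KO 2 also had abundant Xist (19854 and 18386 reads), while SUMO-KO 1, highest on this component, had 51 Xist reads. WT 2, the remaining library with abundant Xist, was at 20.8 on this component, with 11994900 reads. Whether depth, sex or another property sets these libraries apart was not tested.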

How the results depend on the processing

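Settings with a covariate for cortical genes, male libraries only, or without a pair of WT or SUMO-KO libraries were chosen only after the result was seen. No called gene named by the rule changed direction under any setting run. Of 2424 medians of called lists under other settings, 24 took the other sign, and the cause was not tested. With the cortical covariate the median interactions of projection neuron and direct pathway genes went from -0.22 and -0.14 to 0.11 each. The cortical median in Q175HD_SUMO-KO against SUMO-KO went from 0.34 to -0.05 in male libraries only. With the cortical covariate it went to -0.11, but that covariate is the mean of this same list and largely removes its difference by construction. In Q175HD against WT the covariate took microglia from 0.13 to -0.01, oxidative phosphorylation from 0.08 to -0.12 and ribosomal proteins from 0.14 to -0.02. With a mean count of at least 50, which leaves fewer of its genes, the developmental list had medians from -0.13 to -0.06 in all pairs of genotypes but SUMO-KO against WT. For the interaction, choroid plexus genes went from 1.69 to -2.54 without WT 1 and 2, heat shock genes from 0.22 to -0.07 without SUMO-KO 1 and 2, and myelinating oligodendrocyte genes from -0.16 to 0.02 without Q175HD 2 and 0.08 in male libraries only. In Q175HD against SUMO-KO ependymal genes went from -0.77 to 0.17 without SUMO-KO 1 and 2. Counts of calls changed by more than 1.5 times in the settings given here, and the cause was not tested except where fewer libraries or genes entered. With limma voom and sample quality weights the counts were 1855 in Q175HD against WT, 349 in SUMO-KO against WT, 26 in Q175HD_SUMO-KO against Q175HD, 3185 in Q175HD_SUMO-KO against SUMO-KO, 3811 in Q175HD_SUMO-KO against WT and 4028 in Q175HD against SUMO-KO. DESeq2 gave 250 in SUMO-KO against WT, 19 in Q175HD_SUMO-KO against Q175HD and 31 for the interaction. No low-count filter gave 119, 18 and 2 in the same order, and a mean count of at least 50 gave 2 in SUMO-KO against WT. With only the 6 libraries compared the counts were 1297 in Q175HD against WT, 0 in SUMO-KO against WT, 11 in Q175HD_SUMO-KO against Q175HD and 407 in Q175HD_SUMO-KO against SUMO-KO. A fold minimum of 0.5 gave 992 in Q175HD_SUMO-KO against WT. With the cortical list mean as a covariate the counts were 186 in Q175HD against WT, 0 in SUMO-KO against WT, 1 in Q175HD_SUMO-KO against Q175HD and 747 in Q175HD_SUMO-KO against WT. Without WT 1 and 2 they were 68, 0 and 190 in the comparisons of Q175HD, SUMO-KO and Q175HD_SUMO-KO with WT. Without SUMO-KO 1 and 2 they were 1 in SUMO-KO against WT, 619 in Q175HD_SUMO-KO against SUMO-KO, 326 in Q175HD against SUMO-KO and 2 for the interaction. In these fits the lone library is assumed to vary like the other groups. Male libraries only gave 365 in Q175HD against WT, 0 in SUMO-KO against WT, 3 in Q175HD_SUMO-KO against Q175HD, 572 in Q175HD_SUMO-KO against SUMO-KO, 458 in Q175HD_SUMO-KO against WT and 682 in Q175HD against SUMO-KO.

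Leaving out 1 library at a time gave 210 to 593 calls in Q175HD against WT, 0 to 1422 in SUMO-KO against WT, 1 to 6 in Q175HD_SUMO-KO against Q175HD, 747 to 2395 in Q175HD_SUMO-KO against SUMO-KO, 674 to 1160 in Q175HD_SUMO-KO against WT, 475 to 3933 in Q175HD against SUMO-KO and 0 to 34 for the interaction. The median size difference of the knock-in effect ranged from 0.0468 to 0.172, with a limma fry p from 0.00465 to 0.607. SUMO-KO 3 had the lowest voom weight, 0.28. Of the 29 lists, an estimated correlation left 3 called and fry 8 in Q175HD against WT, 4 and 6 in Q175HD_SUMO-KO against SUMO-KO, 4 and 10 in Q175HD_SUMO-KO against WT, and 2 and 7 in Q175HD against SUMO-KO. Each left 0 in SUMO-KO against WT, in Q175HD_SUMO-KO against Q175HD and for the interaction. Of the named genes called in Q175HD against WT, 24 of 61 were called under every planned setting, and 44 of 74 in Q175HD_SUMO-KO against SUMO-KO. With the replicate number as a replicate block the counts were 791, 6, 4, 1704, 1693 and 2094 in the order of the voom counts above, and 0 for the interaction. They shared 641, 4, 4, 1336, 1417 and 1563 genes with the 699, 8, 6, 1389, 1502 and 1594 called without the block, and in SUMO-KO against WT Rian and Ighm were among the genes not shared. Same-numbered libraries of different groups correlated above 0.1 in 11 of 18 pairs, from -0.23 to 0.57. All 3 pairs of WT and Q175HD_SUMO-KO did (0.18, 0.32 and 0.11), where the block gave 1693 calls against 1502, and 10 of 12 libraries had their best match in another group under their own number. These values hint at pairing, but nothing in the labels says that numbers pair the libraries. Number 2 was also the library with abundant Xist in WT, SUMO-KO and Q175HD_SUMO-KO, so sex can add to its matches. Pairs among these 3 libraries correlated at 0.4, 0.32 and 0.08. Q175HD 2, without abundant Xist, correlated with them at -0.06, -0.15 and 0.14. In simulated data at this depth, with changed genes drawn from a mean count of at least 50, 30 of 100 changed 1.5-fold were recovered for Q175HD against WT. For the interaction 12 of 100 were, so small changes were largely missed in these runs. The share missed in the real data, where each gene has its own spread, was not measured.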

Other observations

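The genes described in this part, and the test of a response that SUMO-1 loss undoes, were chosen only after the results were seen, while the edgeR comparisons and interactions were planned and the test of crowding on the genome was written before its result. Averaged over Htt status, which was not among the 7 planned comparisons, SUMO-1 loss changed 14 genes by edgeR, 10 up and 4 down. They include the small Cajal body RNA Scarna2 (log2 fold change 1.13, SE 0.14), the imprinted noncoding RNA Rian (0.66, SE 0.08) and the zinc finger gene Zfp518a (-0.57, SE 0.08), of which all but Rian are named here after their values were seen.

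Gabra2 and Nnt were lower in all 3 Q175HD libraries than in the other 9, and in Q175HD_SUMO-KO against WT their log2 fold changes were -0.05 (SE 0.18) and -0.17 (SE 0.09). Both genes are known to carry variants private to some C57BL/6 substrains, so a strain background of the Q175HD animals is a candidate explanation. Wdfy1, examined for the same question, was at 21.55 to 24.3 CPM in Q175HD and 48.01 to 58.61 CPM in 8 other libraries, but at 21.53 CPM in WT 2 (interaction 0.98, SE 0.36, edgeR adjusted p = 0.997), so its low values are not private to Q175HD. The 50 genes with the smallest p in Q175HD_SUMO-KO against Q175HD held 5 pairs within 2 Mb, against a median of 3 in random draws (permutation p = 0.215), which leaves it open. A response to the knock-in that SUMO-1 loss undoes needs an interaction, and the interactions were 1.17 (SE 0.26, edgeR adjusted p = 0.548) for Gabra2 and 0.46 (SE 0.13, edgeR adjusted p = 0.757) for Nnt. If SUMO-1 loss undid knock-in effects in general these would be smaller without it, but over 3001 genes called for the averaged knock-in effect they were larger by a median of 0.0944 (limma fry p = 0.0333, two-sided rotation test, n = 12 libraries). This size difference did not pass without WT 2, WT 3, Q175HD 1, Q175HD 2 or Q175HD_SUMO-KO 2 (limma fry p up to 0.607, without WT 3, n = 11 libraries). It therefore leans only weakly against a general form, and it leaves a form limited to these genes open. These explanations cannot be told apart here, because every Q175HD library has low values, and substrain genotypes of the animals would separate them.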
